A study of Mus musculus with 2161 samples.

How the data were processed

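The data are single-cell H3K27ac profiles of 2161 mouse embryonic stem cells (V6.5), made with CoBATCH, in which an antibody (Abcam, ab4729) directs a fusion of Protein A and Tn5 to the mark. Per the labels' protocols, the culture medium was a mix of DMEM/F12 and neurobasal that held either 2i or 15% serum, the cells were dissociated with 0.1% trypsin and used directly, and libraries were selected for 200 to 1000 bp. Per the submitters' processing notes, the genome build was mm10 and the tools named were CASAVA 1.8.2, Bowtie2 2.3.1, Picard and bedtools 2.25.0; the role and settings of each are not given in the sources used here.

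Each deposited file is a list of aligned mates of a single cell with chromosome, start, end, read name, a mapping quality score and strand, with no counts or normalization by the authors. The 25858854 lines were joined by read name into 12929427 fragments, at 2 lines per fragment, and every file held both mates of each fragment on opposite strands of 1 chromosome. Mapping quality lay between 31 and 44, so reads with poor or several placements were absent, which lowers the count in repeats and recent gene copies. Fragments were 45 to 2000 bp long, with a median of 413 bp. Cells held 1749 to 77414 fragments. Of all fragments, 1962 (0.0152%) repeated a position within their cell. Read names showed 1 sequencing lane, and no reads were filtered further.

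A fragment was placed at its midpoint. Background was the median density of 10 kb bins with at least 1 fragment on chromosomes 1 to 19, which was 0.8 fragments per kb; the mean density was 5.18. Densities of windows are given as FPKM and were computed here as fragments per kb for every 1000000 pooled fragments. Because a background this low makes 4 times background only 12.8 fragments per 4 kb window, counts over 4 times the mean (82.8 fragments) are given beside it. Genes came from the RefSeq table for GRCm38.p6, the assembly that mm10 names, with 21631 of its 21900 protein-coding genes on chromosomes 1 to 19 and X. The table gives the extent of a gene and neither strand nor transcript starts. The design fixed before the data were examined called for promoters at the most upstream start, and for random lists matched on GC content. In their place stood windows 2 kb either side of the gene end with more fragments (the lower coordinate in a tie), and matching on deciles of gene length. The gene nearest to a super-domain was the nearest gene body to its middle.

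Enriched regions were touching 1 kb bins with at least 10 fragments and at least 4 times background. For the share of fragments in regions and the density near gene ends, regions or ends were chosen in the odd-numbered cells and counted in the even-numbered ones, and the reverse. The share is the average of the 2 sets, and its interval is the mean of their exact bounds. Super-domains came from regions over 2 kb from a gene end, stitched within 12.5 kb and ranked by fragments over background. Fragments were counted over the whole span of a domain, gene ends inside it included. The limit lay where the rank curve, scaled to its highest value, has slope 1. This passed 297 domains, 925 without the densest 10 kb bin, 1319 without the densest 0.1% of bins and 582 when all regions were stitched. The correlation used 5 kb bins and log2 of the count per 1000000 fragments plus 1. For the share of cells with a fragment, cells were thinned to 2000 fragments, the largest multiple of 1000 that 90% of cells reach, which kept 2135 cells and left out 26. Variation between cells was the observed variance of a window's counts over the variance a Poisson model with each cell's depth gives, for windows with at least 200 fragments.

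The labels give 1 group and tie no cell to a culture, plate or donor, so cells were not used as replicates, no test between groups or across cells was made and no SD between replicates can be had. Values carry exact Poisson intervals for counts and exact binomial (Clopper-Pearson) intervals for shares, at 95%, which cover counting error only, and a count or share of 0 is given its exact upper bound, with 3 counts as the floor of a window. Cells were not clustered or filtered, and no doublet caller was run. Gene lists were fixed before the data were examined: naive, core and general, and formative and primed pluripotency, serum-associated signalling, neuroectoderm, mesoderm, endoderm, trophoblast, 2-cell-like state, Hox clusters, housekeeping, fibroblast and feeder, blood, liver, germ cell and meiosis, imprinted, chromatin enzymes, cell cycle and olfactory receptors. Of the listed symbols, 1 was not found in the gene table. Genes were named by a rule set at the same time: 13 fixed genes, the 2 highest and the lowest of each list, the 10 densest windows, the 10 most variable windows and the 10 top super-domains.

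Alternatives fixed in advance collapsed repeated positions, weighted cells equally, left out the cells with the most fragments or the densest bins, and changed the window, background, threshold, bin, stitching, pseudocount and thinning. Others, chosen after the data were seen, changed how the gene end was chosen and left out shared windows, the single densest bin or cells with few fragments in enriched regions. The window counts were tested on simulated fragments for 21635 genes, of which 200 were raised. The simulated background was even, at 0.8 fragments per kb, and the raised genes were long, far from other gene ends and raised at their lower coordinate. Genes raised 8, 32 or 128 times were found over 4 times background in 100% of cases and genes raised 2 times in 2%. Of the unraised protein-coding genes 0% passed, which an even background this far under the limit all but fixes. Uneven background, shared windows and starts inside a gene were not simulated. The variation ratio came out at 0.999 with no added variation. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.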

Results

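H3K27ac, the acetylation of histone H3 at lysine 27 that marks active promoters and enhancers, was profiled in single mouse embryonic stem cells of the V6.5 line. The assay was CoBATCH, in which a fusion of Protein A and the Tn5 transposase is brought to chromatin by an antibody and cuts and tags the DNA there. The cells, called native in the labels, form a single group with no control antibody, input or second condition. The labels state a culture with 2i (kinase inhibitors that hold stem cells in the naive state) or with 15% serum, and not which cell had which. The files held 12929427 fragments, with a median of 4048 per cell, quartiles of 2760 and 6806 and a highest value of 77414. The tenth of cells with the most fragments held 32.9% of them. The labels tie no cell to a culture, plate or donor, so the cells were summed as 1 sample and there are no replicates. No p-value is given, and all intervals are 95% intervals that cover counting error only.

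The question the design allows is where the fragments lay in these cells, and it was put first to genes of pluripotency. Without a control antibody or input, cuts at the mark cannot be told apart from cuts made without it. Pou5f1, which encodes the core pluripotency factor Oct4, had the densest gene-end window of all protein-coding genes, at 78.2 FPKM (exact Poisson interval 75.8 to 80.6). FPKM stands here for fragments per kb of window for every 1000000 fragments of the pooled cells. Sox2, its partner factor, had 41 FPKM (39.3 to 42.8). All 30 measured members of the naive and core pluripotency lists lay over 4 times the background of 0.0619 FPKM, and their median was 21.4 FPKM. Most genes passed this limit, with 74.8% of all protein-coding genes over it. Windows were 4 kb long and centred on whichever end of the gene held more fragments, because the gene table used here gives no strand.

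Among the naive factors, Tbx3 (35.5 FPKM, 33.9 to 37.2) and Klf2 (30.3 FPKM, 28.8 to 31.9) were the highest. Zfp42, also called Rex1, had 21.6 FPKM (20.3 to 22.9), Klf4 had 21.3 FPKM (20.03 to 22.6) and Nanog had 9.57 FPKM (8.75 to 10.5). Esrrb had 3.06 FPKM (2.60 to 3.57) and Nr5a2, the lowest of this list, had 0.773 FPKM (0.553 to 1.05). In the core list, Trim28 followed Pou5f1 with 41.5 FPKM, in a window that also held an end of the predicted gene Gm31649, and Dppa2 was the lowest at 0.735 FPKM (0.520 to 1.01). The median was 15.7 FPKM for the 15 naive genes and 23.05 FPKM for the 15 core genes. Of 10000 random lists of protein-coding genes matched on gene length, 1 had a median as high as that of the naive list and 0 as high as that of the core list. This was not particular to pluripotency genes, since it was 0 for the housekeeping and chromatin enzyme lists and 8 for the cell cycle list. Measured against 4 times the mean density of 0.400 FPKM, 27 of the 30 genes passed, against 58.1% of all protein-coding genes.

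Genes of later lineages carried fewer fragments at the median, with overlap between single genes. The 51 measured germ layer and trophoblast genes had a median of 1.59 FPKM, so that the pluripotency median was 13.5 times as high. T, the mesoderm factor Brachyury, had 1.64 FPKM (1.31 to 2.03) in a window shared with an end of the predicted gene LOC115486424. The endoderm factors Sox17 and Gata6 had 2.75 FPKM (2.31 to 3.24) and 1.95 FPKM (1.59 to 2.37), the eye and neural factor Pax6 had 1.59 FPKM (1.26 to 1.97), and the trophoblast factor Cdx2 had 2.98 FPKM (2.53 to 3.49). The upper bounds of these genes lay under the lower bound of Nanog, but the neural genes Sox1 and Tubb3 lay over Nanog. Among naive factors, Nr5a2 lay lower than all of these lineage genes by its end window. Such a window undercounts a gene whose start lies inside its listed extent. Esrrb was level with Cdx2 by its end window, which leaves out most fragments at Esrrb.

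The count of lineage genes over background depended on the background. Over 4 times the median background lay 43 of the 51 genes, and over 4 times the mean density 24 of them. Of all protein-coding genes, 74.8% and 58.1% passed these limits. By list, the median was 1.92 FPKM for neuroectoderm, 1.53 for mesoderm, 1.31 for endoderm and 0.580 for trophoblast. Of the 10000 matched random lists, 6819, 6038, 8725 and 9438 had a median as high, in that order. The highest members were Sox1 (12.9 FPKM) and Tubb3 (11.6) in neuroectoderm, Tbx6 (7.42) and Eomes (3.96) in mesoderm, Sox7 (3.06) and Sox17 in endoderm, and Ascl2 (4.25) and Tfap2c (4.22) in trophoblast. The windows of Tubb3 and Tbx6 also held ends of Mc1r and Ypel3. The lowest were Lhx2 (0.425 FPKM), Msgn1 (0.290), Cdh6 (0.0193, from a single fragment) and the placental hormone gene Prl3d1, with 0 fragments and an exact upper bound of 0.0713 FPKM.

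Formative and serum-associated genes lay at the median between the pluripotency genes and the 1.59 FPKM of the germ layer and trophoblast genes. The medians of Hox genes and of genes of the 2-cell-like state lay under that value. The Hox median still lay over the 0.580 FPKM of the trophoblast list alone. The 12 formative and primed genes had a median of 4.79 FPKM, with 10 over 4 times background and 8 over 4 times the mean. Tcf15 (15.1 FPKM) and Otx2 (13.2 FPKM, 12.3 to 14.3) were the highest of them, Fgf5 had 1.26 FPKM (0.970 to 1.60) and Cer1 had 0.0773 FPKM (0.0211 to 0.198). All 13 serum-associated genes passed both limits, with a median of 7.56 FPKM, led by Nodal (24.6) and Myc (24.5), with Krt18 the lowest at 1.89. The 39 Hox genes all lay over 4 times background, but 6 lay over 4 times the mean, and their median was 1.102 FPKM. Hoxd8 was the lowest Hox gene, at 0.309 FPKM. None of the 8 measured genes of the state that resembles the 2-cell embryo passed either limit, and 6 of them, Zscan4f included, had no fragment. Usp17ld had 0.0580 and Zfp352 had 0.0387 FPKM, at or under the floor of 3 counts per window. Reads with several placements were absent from the files, which can lower counts in recent gene copies. Low counts in this list therefore do not show that the mark was missing.

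Marker genes of other cell types were mostly low. The median was 0.870 FPKM for 16 fibroblast and feeder genes, 0.348 for 12 blood genes, 0.135 for 9 liver genes and 0.570 for 10 germ cell and meiosis genes. Over 4 times background lay 11, 8, 3 and 9 of them, and over 4 times the mean density 6, 3, 2 and 1. Loxl1 (5.45 FPKM) and Thy1 (2.51) were the highest fibroblast genes. The highest blood genes, Cd79a (3.77) and Cd4 (2.82), and the highest liver gene, Apoa2 (19.1), had windows that also held ends of Arhgef1, Gpr162 and Tomm40l, while Apoa1 (2.82) did not share its window. Dazl (1.68) and Stra8 (1.57) led the germ cell list and Ddx4 had 0.193. Dcn, Ptprc and Alb, which encode decorin, the blood cell antigen CD45 and albumin, each had 0 fragments. Olfactory receptor genes, used here as a low reference, had no fragment in 65.2% of windows, Olfr998 among them, and 3.24% lay over 4 times background. The highest, Olfr94 (7.60 FPKM) and Olfr1393 (1.62), shared their windows with ends of Ubd and Mgat1.

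**Figure D1:**
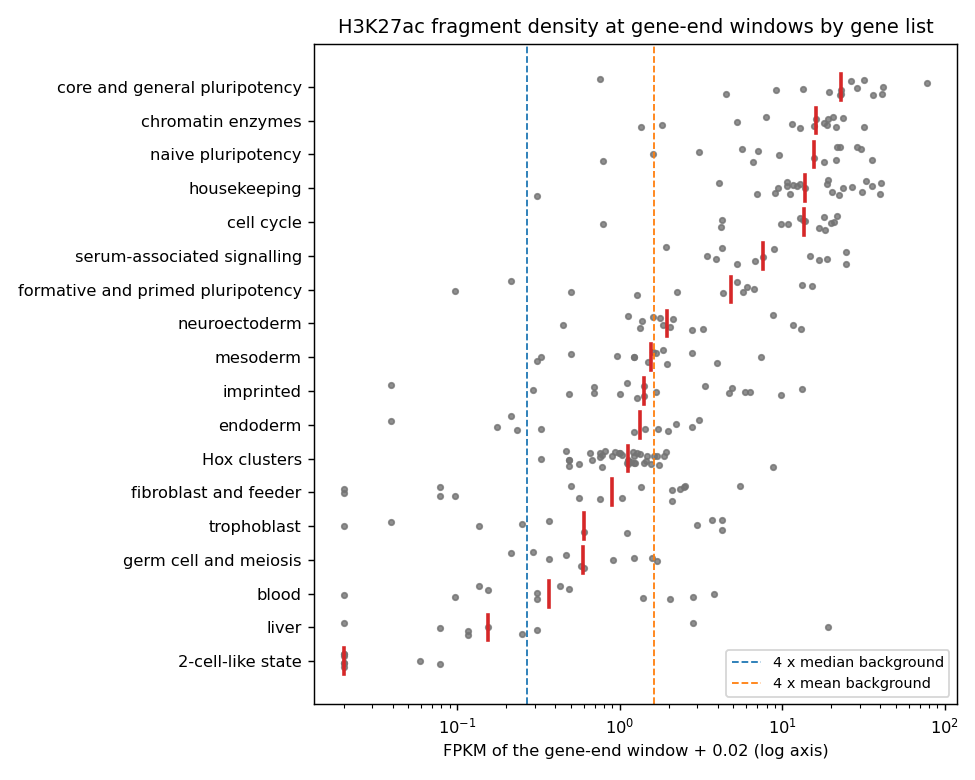
Each grey point is a gene of a list, placed by the FPKM of its gene-end window plus 0.02 on a log axis, with the vertical jitter carrying no information. Red bars are list medians, from 0 for the 2-cell-like state to 23.05 FPKM for core pluripotency, and dashed lines are 4 times the median background of 0.0619 and 4 times the mean of 0.400 FPKM.

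Across all 21631 protein-coding genes on chromosomes 1 to 19 and X, 16178 (74.8%) lay over 4 times background and 12574 (58.1%) over 4 times the mean. After Pou5f1, the densest windows were those of Ankrd10 (76.4 FPKM), Gm33049 (67.6) and Pim3 (61.9), which overlap, Ptma (62.2), Fzd5 (57.4), Klf12 (55.05), Junb (54.5), Sall1 (53.6) and Lamc1 (52.6). The 23 housekeeping genes had a median of 13.9 FPKM and all lay over 4 times background, with 22 over 4 times the mean. Ncl (40.3) and Tubb5 (39.7) were the highest of these and Ywhaz (0.290) the lowest. A gene whose start lies inside its listed extent is undercounted by a window at its ends. An end of another protein-coding gene lay in 22.4% of the windows. When those windows were left out, 11590 of the remaining genes passed the limit of 4 times background. That count is out of fewer genes than the 21631 above.

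Fragments gathered near gene ends and in enriched regions. Their density within 1 kb of the denser gene end was 9.66 times that at 9 to 10 kb, with the end chosen in other cells than those counted. Per cell the median was 10.4, with quartiles of 8.81 and 11.9. When both ends of each gene were counted, the pooled ratio was 4.80. In all, 76761 enriched regions covered 163.1 Mb, or 6.20% of the covered length. With the mean density as background there were 44522. Of the regions, 27.2% lay within 2 kb of a gene end and held 64.3% of the fragments in regions, and 61.05% of the 55885 others lay inside a protein-coding gene.

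The share of fragments in regions found in the other cells was 78.92% (78.89 to 78.96) when the odd-numbered and even-numbered cells were averaged. It was 81.2% (81.19 to 81.25) in the odd-numbered and 76.6% (76.59 to 76.66) in the even-numbered cells, a gap far wider than these exact binomial intervals, which leave out the spread between cells. Per cell the median was 87.5%, with quartiles of 84.1% and 90.1% and a range from 1.197% to 96.04%. In 88 cells (4.07%) the share was under 50%, and these held 12.03% of all fragments. Counts in 5 kb bins of the odd-numbered and even-numbered cells had a Pearson r of 0.972 on the log2 scale and a Spearman rho of 0.835, across 526304 bins, which are not independent replicates.

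**Figure D2:**
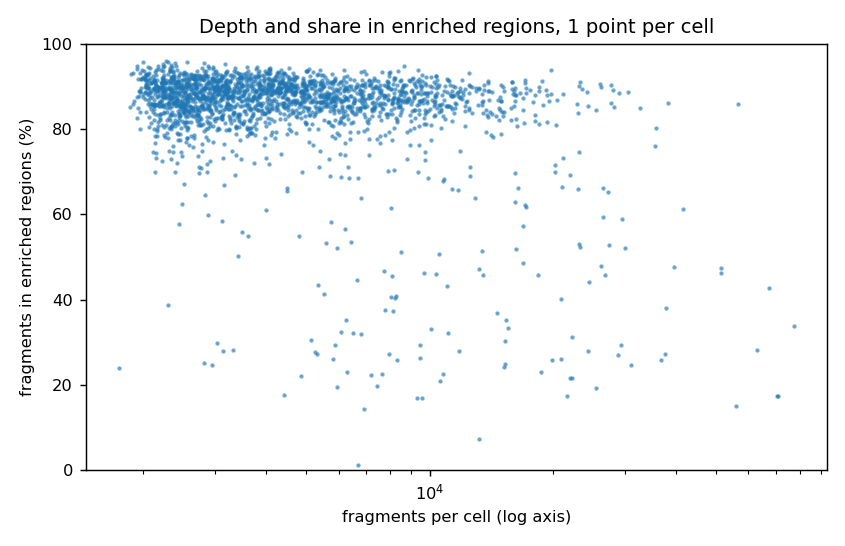
Each point is a cell, with its number of fragments on a log axis and the percentage of its fragments in enriched regions found in other cells. Most cells lie near the median of 87.5%, and 88 lie under 50%.

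Some genes of the pluripotency lists overlapped, or were the nearest gene to, long domains stitched from distal regions. Distal regions were stitched into 21727 domains, of which 1.37% passed the rank limit for super-domains and held 27.7% of the domain fragments. Fragments were counted over the whole span of a domain, so those at gene ends inside the span were included. Of all protein-coding genes, 1.98% were the nearest gene of a super-domain or overlapped one. Of the 15 naive genes 3 did (Esrrb, Tbx3 and Tfcp2l1), of the 15 core genes 4 did (Sox2, Lin28a, Mycn and Jarid2), and Dnmt3a, Tcf15, Myc, Dnmt1 and Mcm5 of other lists did too. None of the 51 germ layer and trophoblast genes did, which says little, because few would be expected at the share of all genes. It also rests on the rule for the nearest gene. The domain ranked 28, at chromosome 8, 12406001 to 12569000, begins close to Sox1, which ends at 12399555. Spaca7 was nearer to its middle, at 85.5 kb. Tcf15, Mycn and Myc overlapped no super-domain and were only the nearest gene, 26.4, 124.1 and 109.6 kb from its middle. The super-domains at Sox2, Lin28a and Mcm5 include the gene's own end window. Without the fragments of that window, each would lie under the rank limit. Those at Tbx3, Jarid2, Esrrb and Dnmt3a also include their gene's end window, and would still pass. No enrichment was tested. The number that passed rested on a single place: the top domain, at chromosome 17, 39843001 to 39849000 (mm10), held 116267 fragments against 23146 in the next, and overlaps a pseudogene of the 18S ribosomal RNA, Rn18s-rs5. Without the 10 kb bin that holds it, 4.26% of domains passed, and the list genes at super-domains were not counted again there.

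The nearest protein-coding gene to that domain was Esp38, 104.5 kb away, and each of the next domains overlapped the gene named for it. The domain at Gse1 spanned chromosome 8, 120172001 to 120544000, and that at Zfp423 chromosome 8, 87608001 to 88034000, both overlapping the gene. Domains also overlapped Kazn, Tns3, Mapt, Septin9 and Zmynd8. The domain at chromosome 1, 86414001 to 86515000 overlapped Tex44, with its middle 36.5 kb from the gene, and that at chromosome 12, 86748001 to 86874000 overlapped Lrrc74a, with its middle 41.98 kb away. The domain over Esrrb, at chromosome 12, 86419001 to 86527000, ranked 11.

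**Figure D3:**
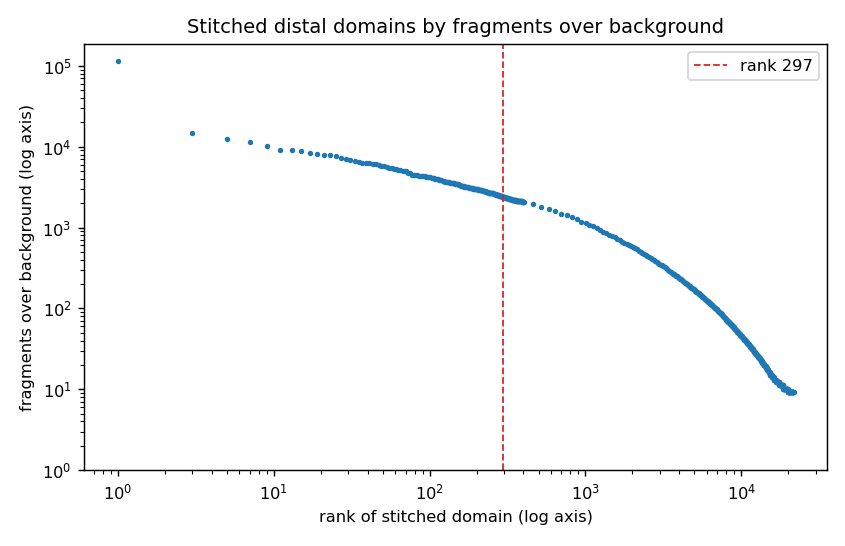
Stitched distal domains are ranked by fragments over background, with both axes on a log scale and a sample of the ranks drawn as points. The dashed line marks the rank limit, where a domain held 2375 fragments over background, and the first point, at 116262, stands apart.

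In single cells, pluripotency windows were found more often than lineage windows at the median, and single genes overlapped. At 2000 fragments per cell, Pou5f1 had a fragment in 48.9% of cells (exact binomial interval 46.8 to 51.04), Sox2 in 30.4% (28.5 to 32.4), Klf4 in 18.8% (17.1 to 20.5) and Nanog in 7.17% (6.11 to 8.34). Lower shares were those of Esrrb at 2.48% (1.86 to 3.23), Dppa2 at 0.656% (0.359 to 1.098) and Nr5a2 at 0.609% (0.325 to 1.04). The Esrrb share is that of its end window, which leaves out most fragments at this gene. Among lineage genes, Sox1 was found in 10.3% (9.05 to 11.7), Tubb3 in 8.48% (7.33 to 9.74) and Tbx6 in 6.65% (5.63 to 7.79). Sox17 was found in 2.01% (1.46 to 2.70), Cdx2 in 2.67% (2.03 to 3.45), Gata6 in 1.55% (1.07 to 2.16) and Pax6 in 1.26% (0.835 to 1.83). The median over genes was 17.1% for the 30 pluripotency genes and 1.12% for the 51 germ layer and trophoblast genes, and the mean over olfactory receptor genes was 0.0235%. The 26 cells with fewer fragments were left out here. Without thinning, the pluripotency median was 36.1%, so the share depends on depth and a cell without a fragment does not show that the mark is missing. A window found in 0 cells, such as that of Alb, allows a share of up to 0.173% at this depth, by the exact binomial bound.

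Counts in gene-end windows varied between cells somewhat more than depth and counting give. Ankrd10 had the highest ratio of observed to expected variance, 1.98, followed by Gm33049 (1.89), Pou5f1 (1.88), Ptma (1.84), Pim3 (1.81), Klf12 (1.801), Sall1 (1.75), Gm20783 (1.70), Ing1 (1.69) and Gm35364 (1.69). The windows of Gm20783 and Gm35364 also held ends of LOC108167694 and Ctbp2. The median over 9557 windows with at least 200 fragments was 1.15, and the 5th and 95th percentiles were 1.03 and 1.37. The ratio went up with the number of fragments, from a median of 1.08 in windows with the fewest, from 200 on, to 1.28 in those with the most, up to 4042. Ankrd10, Gm33049, Pou5f1, Ptma, Pim3, Klf12 and Sall1 were also among the 10 densest windows. The ranking was not adjusted for density, so it does not show that these genes vary more than others of like density. Without the 88 cells under 50% in enriched regions the median ratio over windows was 1.05.

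Chromosome 11 had the highest median share of fragments per cell, 8.89%, followed by chromosomes 7 (7.84%) and 8 (7.84%), and X had 1.36%. Among windows over 4 times the mean density, those on chromosome 8, which include Ankrd10, Junb, Sall1, Ing1, Zfp42 and Klf2, held a median number of fragments 1.36 times that of all autosomes. The ratio was 1.16 on chromosome 1, 1.14 on chromosome 17, 0.820 on chromosome 18 and 0.667 on X. Chromosome Y held 0.0180% of all fragments and the mitochondrial genome 0.0141%.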

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

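The tests of gene density per chromosome, depth, barcode errors, stray fragments and even coverage were chosen after the result was seen. The whole-chromosome ratio of chromosome 8 was also known before its other tests were set. The labels give a single group, so no biological explanation was tested by comparing groups. An extra copy of chromosome 8 and a mixture of the cultures that the labels name were tested within the group, and both stay open.

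Fragments outside the assembled chromosomes were not used in any comparison. There were 8960 of them (0.0693% of all), on 32 unplaced or unlocalised sequences, above the 3 counts that a count of 0 allows. A single sequence held 7582 of these (84.6%), and 84.6% of cells had a fragment on it.

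Active windows on chromosome 8 held 1.36 times the fragments of the autosomal median. A few cells did not produce this, since the ratio was 1.38 with each cell weighted equally. A higher density of active genes is argued against by 3 of the 4 autosomes with more active windows per Mb, whose ratios lay under 1.1. An extra copy of chromosome 8 in most cells remains a candidate explanation that these data do not settle: along the chromosome, in 4 parts of equal length, the ratios were 1.11, 1.199, 1.61 and 1.29. Outside enriched regions the ratio was 1.13, and other autosomes ranged there from 0.828 to 1.26.

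The share of fragments in enriched regions differed between cells, from 1.197% to 96.04%. Low depth did not go with a lower typical share: the median was 1.82 percentage points higher in the shallowest of 4 equal sets of cells than in the deepest. Medians of such sets cannot show the few cells with low shares. The cells under 50% were 4.07% of cells and held 12.03% of all fragments. The 10 cells with the lowest shares held 4410 to 70926 fragments, against a median of 4048 in all cells. These values argue against low depth for those cells as a set. Stray fragments drawn from the pool of all cells move a share toward the pooled 78.86% and not past it. They alone would therefore not give the lowest shares. The test of this added nothing: the 88 cells (4.07%) with an exact upper bound under 50% were already known to lie under it. Stray fragments from outside these cells were not covered. Perfectly even coverage was not seen in the 10 cells with the lowest shares (1.197% to 17.7%), where chromosome shares differed from chromosome lengths by a median of 15.5%, against 16.1% in all cells pooled. Even coverage in cells with lost or gained chromosomes would give such a value too and may still account for part of the pattern. For the smaller differences, fragments that reached wrong cells through barcode errors stay open. The test chosen for them decides nothing: 9.86% of cells had an exact upper bound under the pooled share, but that share is the mean of the same cells weighted by their fragments, so some had to lie under it.

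Window counts varied between cells more than depth and counting give, with a median ratio of 1.15. When the expected counts came from each cell's fragments in enriched regions instead of all its fragments, the median was 1.05 and 32.05% of the excess over 1 was left. This is consistent with most of the excess coming from the differing share in regions. A mixture of 2i and serum cultures cannot be told apart from none: of the formative and serum-associated lists, 0 had a median variation above the 95th percentile of random lists matched on fragments, but they lay at percentiles 92.4 and 94.03, with 7 and 11 genes.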

How the results depend on the processing

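Alternatives that changed the gene-end choice, left out shared windows, the single densest bin or cells under 50% in enriched regions were chosen after the data were seen. No paired analysis was possible because there is a single group. Of 82 alternative values, 53 stayed within the counting interval of the main value, or within 1.5 times for a count, and 29 did not. Counting intervals are narrow at this depth, so many of the 29 are small shifts, and unless stated the cause was not tested. The start of a gene with the highest density was not run, for want of transcript starts, and olfactory windows as background gave no value, their median being 0. The limit of 8 times background moves nothing for regions, the share in them and super-domains, because the minimum of 10 fragments per bin is higher.

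The density ratio near gene ends, 9.66, was 10.1 with cells weighted equally, 10.1 without the tenth of cells with the most fragments, 14.7 within 500 bp against 4 to 5 kb, 4.80 at both ends and 10.2 without cells under 50% in regions. The share in regions, 78.9%, was 77.9% with the mean background, 84.04% with 2 kb bins, 80.4% without the deepest cells, 77.5% without the densest 0.1% of bins and 83.98% without cells under 50%, the last by construction. Regions numbered 44522 with the mean background. Super-domains, judged by their number and given as a percent of the stitched domains of each run, were 1.37% in the main run, 0.709% with stitching within 5 kb (where their number stayed within 1.5 times), 2.51% from all regions, 6.07% without the densest 0.1% of bins and 4.26% without the densest bin alone, which scales the rank curve. The correlation, 0.972, was 0.978 in 10 kb and 0.955 in 1 kb bins, 0.923 with a pseudocount of 0.1, 0.835 as Spearman rho, 0.970 without the densest bins and 0.979 without cells under 50%. Germ layer windows over 4 times background fell from 43 to 24 with the mean background. The share of cells at pluripotency windows, 17.1%, was 12.51% with 1 kb either side, 36.1% unthinned and 29.4% at 4000 fragments, where the set of cells changed along with the depth. Variation, 1.15, was 1.14 with 1 kb either side, 1.06 without the deepest cells, 1.33 for windows with 1000 fragments and 1.05 without cells under 50%. The share on chromosome 11 was 8.55% without the densest bins.

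List medians stayed within their interval for 14 of 18 lists with 1 kb either side (14 higher), 15 without the deepest cells (17 lower), 17 with the densest window inside the gene (17 higher) or the mean of both ends (17 lower), and 18 in the other settings. Of 79 named genes, 16 stayed within their interval without the deepest cells (72 lower), 20 with 1 kb either side (56 higher), 20 with the mean of both ends (72 lower), 48 with cells weighted equally (57 higher), 52 with the densest window inside the gene (52 higher), 72 without cells under 50%, 76 with the end chosen in other cells and 79 with repeated positions collapsed. Where cells were left out, densities were fragments per kb and were not rescaled to the fragments that remained. Such densities cannot rise. The deepest cells held 32.9% of all fragments and those under 50% held 12.03%. The lower values without these cells, for lists and genes, therefore follow from the setting. They do not show whether the FPKM values depend on these cells.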

Other observations

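Genes of chromatin enzymes and of the cell cycle had medians under the 21.4 FPKM of the 30 pluripotency genes and over the 1.59 FPKM of the germ layer and trophoblast genes. The chromatin enzyme median lay just over the 15.7 FPKM of the naive list alone. The 15 chromatin enzyme genes had a median of 15.99 FPKM and 14 lay over 4 times the mean density. Tet1, which oxidises methylated cytosine, had 31.9 FPKM (30.4 to 33.5) and the acetyltransferase gene Kat2a had 23.8 FPKM, in a window with an end of Hspb9, while Chd7 had 1.33 FPKM. The 14 cell cycle genes had a median of 13.6 FPKM and 13 lay over 4 times the mean. Pcna (21.5 FPKM, in a window with an end of Cds2) and Mcm5 (20.8) were the highest. Cdkn1a, which encodes the cell cycle inhibitor p21, was the lowest at 0.773 FPKM (0.553 to 1.05).

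Imprinted genes spread widely. Of 18, 17 lay over 4 times background and 8 over 4 times the mean, with a median of 1.39 FPKM. Peg3 (13.2 FPKM, in a window with an end of Usp29) and Zrsr1 (9.75) were the highest, and Snrpn had 0.0193 FPKM from a single fragment, with a listed extent whose ends need not hold its start.

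The 10 kb bin with the most fragments, chromosome 17, 39840001 to 39850000, held 116267 fragments (0.899% of all), 18.7 times the bin ranked next, and overlaps Rn18s-rs5 and the long non-coding RNA gene AY036118. It held more than 4 overlapping fragments in 82% of cells, against 20.5% of cells anywhere else. A locus in a replicated diploid cell has 4 copies. The median overlap per cell was 8 fragments in this bin, and the median of the highest overlap elsewhere was 4. An identical fragment position was found in another cell for 7.48% of fragments. In 62 pairs of cells, 50 or more positions seen in exactly 2 cells were shared. In the pair that shared the most, they were 239.4 times the number that the depths of the pair give. Whether such pairs are the same cell or a doublet was not tested, so the cells, and the odd-numbered and even-numbered sets, need not all be separate.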
